A study of Mus musculus with 2 samples.

How the data were processed

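RNA was profiled from the apex of embryonic mouse hearts at stage E12.5, with tissue of 8 hearts combined for each genotype. The heterozygous control carries the Nkx2-5 Cre driver and 1 floxed copy of Ezh2, and the mutant carries the driver and 2 floxed copies. There is 1 library per genotype, made from total RNA with a kit for full-length transcripts, per the labels' protocols, and the labels call the cells cardiomyocytes without naming a sort. The spread between animals was therefore not measured, differences between genotypes have no replicate check, and no p-value of a genotype effect was computed.

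The deposited table lists 29595 gene models with whole-number read counts for both libraries, per the file headers. The authors' normalized columns are CPM, that is counts per 1e6 reads of the library's own total, and are not scaled for gene length; recomputing them from the counts reproduced each value to within 4.91e-11. The table of the whole series and the tables of single samples held the same counts and CPM in all rows, with 0 rows that differed. The authors' fold is a ratio of heterozygote CPM over mutant CPM, per the file headers. It is blank for every gene model with under 10 reads in both libraries and given for all others, with 0 exceptions, so that 2430 models with reads in both libraries have none. The deposited p-value of each gene model comes with no named test or adjustment, per the file headers. The aligner, the counting program, its use of strand and the genome build are not given in the sources used here. Coordinates are printed as the files give them, with 1 added to the start because starts count from 0. On chromosome 1 they reach 197002909, past the end of the last GRCm38 RefSeq gene at 195291439, so the files use another build than GRCm38 and no coordinates of other tables were joined to them.

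Library totals were 13944617 reads for the heterozygote and 14122579 for the mutant. Rows of 1 symbol were summed, which left 29383 genes, of which 185 had more than 1 row. Gene models named by an mRNA accession instead of a symbol took 5.80% of reads in the heterozygote and 5.79% in the mutant and were kept, but were not named in the text. Overlapping models can count the same reads. Among the genes named, this concerns at least Isl1, Pax6, H2-Ab1, Xist, Ccnd2, Hopx, Slc8a1, Vcan, Hist1h2ao, Hist1h2ag, E130309F12Rik and Cytl1. Without strand a gene and its antisense partner cannot be told apart.

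CPM were recomputed from the counts with TMM scaling, a trimmed mean of log ratios, in edgeR 4.0.16 under R 4.3.3. The factors were 0.970 for the heterozygote and 1.03 for the mutant, and 30% of ratios and 5% of levels were trimmed. The log2 ratio is log2((mutant CPM + 1)/(heterozygote CPM + 1)), which understates differences of genes with few reads. Genes whose higher value was at least 1 CPM were tested for size, and those at least 2-fold apart on this scale were counted. Folds given in the text are plain ratios of scaled counts with a 95% exact conditional Poisson interval. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules and animals were pooled. Where a gene had no read in a library, that count was set to 3. The fold is then given against this floor and is not a bound of the counting interval.

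Before the data were examined, 36 gene lists, the size thresholds, the rule for named genes and most alternatives were fixed. Named genes are Ezh2, Ezh1, Eed and Suz12, the 12 highest and 12 lowest log2 ratios among genes with a symbol, and from each list up to 4 members at least 2-fold apart or else the 2 members with the highest mean; 1 gene that this rule names is not reported here, and counts and medians include it. Of the list entries, 688 matched a symbol, 7 an alias, 8 a synonym, 3 an accession and 174 a name pattern, while 11 were not matched. A list is described by the median log2 ratio of its members at or above 1 CPM and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The random lists were drawn from the 13826 tested genes named by a symbol. For each alternative 1000 random lists were drawn. Percentiles describe these libraries and are not tests of the genotype. Some genes, Isl1, Pax6, Cdkn2a, Cdkn2b, Hcn4 and Bmp10 among them, were put on lists with knowledge of the published study of this mouse, which used these libraries, so their direction is not independent evidence.

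Because log2 ratios followed GC content, an alternative chosen after seeing the data removed a quadratic trend on GC content and log length, fitted to genes with a mean of at least 5 CPM. GC content and length came from the longest GENCODE M21 transcript of each symbol. Of the tested symbols, 13080 (94.6%) had a value; a list with under 80% of its members covered was left out of the comparison of lists under this alternative, which was the case for the mitochondrially encoded genes, with 13 of 35. Other alternatives were the pseudocount, the floor, median-centred, upper-quartile and total-count scaling, DESeq2 1.42.0 size factors, 1.5-fold and 3-fold thresholds, and unmatched random lists. No replicate could be left out.

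The calculations were tested on simulated Poisson counts for the 13826 symbols with the real library sizes, for the mutant against the heterozygote. Of 50 genes changed at each size, 0 were counted as 2-fold apart at a true fold of 1.5, 40 at 2.5, 49 at 4 and 50 at 8, and 0 of 13626 unchanged genes were counted. The counting interval held the true ratio for 95.7% of genes, and 10 of 200 random lists fell outside the central 95%. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.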

Results

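Transcript levels were measured by RNA sequencing in the apex of hearts from mouse embryos at stage E12.5. Each group combined tissue of 8 hearts into 1 library: a heterozygous control with 1 floxed Ezh2 copy, and a mutant with both copies floxed, each with Cre recombinase under Nkx2-5, a gene active in the heart lineage. Ezh2 encodes the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 on lysine 27. The comparison asks which transcripts differ when both copies can be recombined. The libraries held 13944617 reads in the heterozygote and 14122579 in the mutant, over 20310 and 20535 gene models with at least 1 read. With 1 library per genotype no difference below has a replicate check, and every interval is a 95% interval of counting error.

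Ezh2 (chromosome 6, 47480280 to 47545337) was lower in the library labelled mutant, with 319 reads against 493. Its scaled level was 21.9 CPM against 36.4 CPM, a heterozygote-to-mutant ratio of 1.66 (1.44 to 1.92) and a log2 ratio of -0.71. This gene-level value counts reads inside and outside the floxed exons, and the control has 1 floxed copy itself. The other PRC2 core genes differed little: the mutant-to-heterozygote ratio was 0.921 (0.760 to 1.12) for Ezh1, the second catalytic subunit, 0.925 (0.827 to 1.03) for Eed and 0.938 (0.861 to 1.02) for Suz12. The median of the 11 PRC2 subunit genes was -0.09, at percentile 20.4 of matched random lists, and its percentile was 63.5, with a median closer to 0, after removal of the GC trend. Genes of PRC1, the complex that ubiquitinates histone H2A, had a median of 0.24, at percentile 100, with 14 of 18 above 0. Bmi1 was the only PRC1 gene at least 2-fold apart, at 709 against 284 reads (2.32-fold higher in the mutant, 2.02 to 2.67).

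Of 16185 genes with at least 1 CPM in a library, 98 were at least 2-fold higher in the mutant and 28 at least 2-fold lower. The highest ranked with a pseudocount of 1 CPM was Nrn1, which encodes the neuronal surface protein neuritin, with 516 reads against 34 (14.1-fold, 9.96 to 20.6). With a pseudocount of 0.1 CPM its log2 ratio of 3.77 was below those of Cdkn2a (5.46) and Otx2 (5.04). Cdkn2a, the locus of the cell cycle inhibitor p16 and of p19Arf, had 110 reads against 1 (ratio 102, 17.97 to 4073). The axon guidance gene Sema5b was 11.5-fold higher (5.82 to 25.7), the neuronal motor gene Kif1a 4.41-fold (3.33 to 5.93), the MHC class II gene H2-Ab1 4.26-fold (3.09 to 5.999) and the pro-apoptotic gene Pmaip1 8.98-fold (3.89 to 25.5). H2-Ab1 had 211 reads against 46, and a model named IAP that overlaps it, with 26 against 21, can share some of them. Of the 98 genes, 45 were under 1 CPM in the heterozygote and 5 had no read there, and their median level was 1.33 CPM in the heterozygote and 5.36 CPM in the mutant. All 98 and all 28 counting intervals excluded a ratio of 1, which the size rule with its pseudocount brings about by construction at this depth. In 100 simulated pairs of libraries with equal rates, at most 3 genes were higher and 2 lower. These pairs held counting error only, without any spread between pools or preparations. They do not show how far 2 pools of the same genotype would differ. The counts depended on the pseudocount, with 312 higher and 143 lower at 0.1 CPM and 14 and 6 at 5 CPM.

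**Figure D1:**
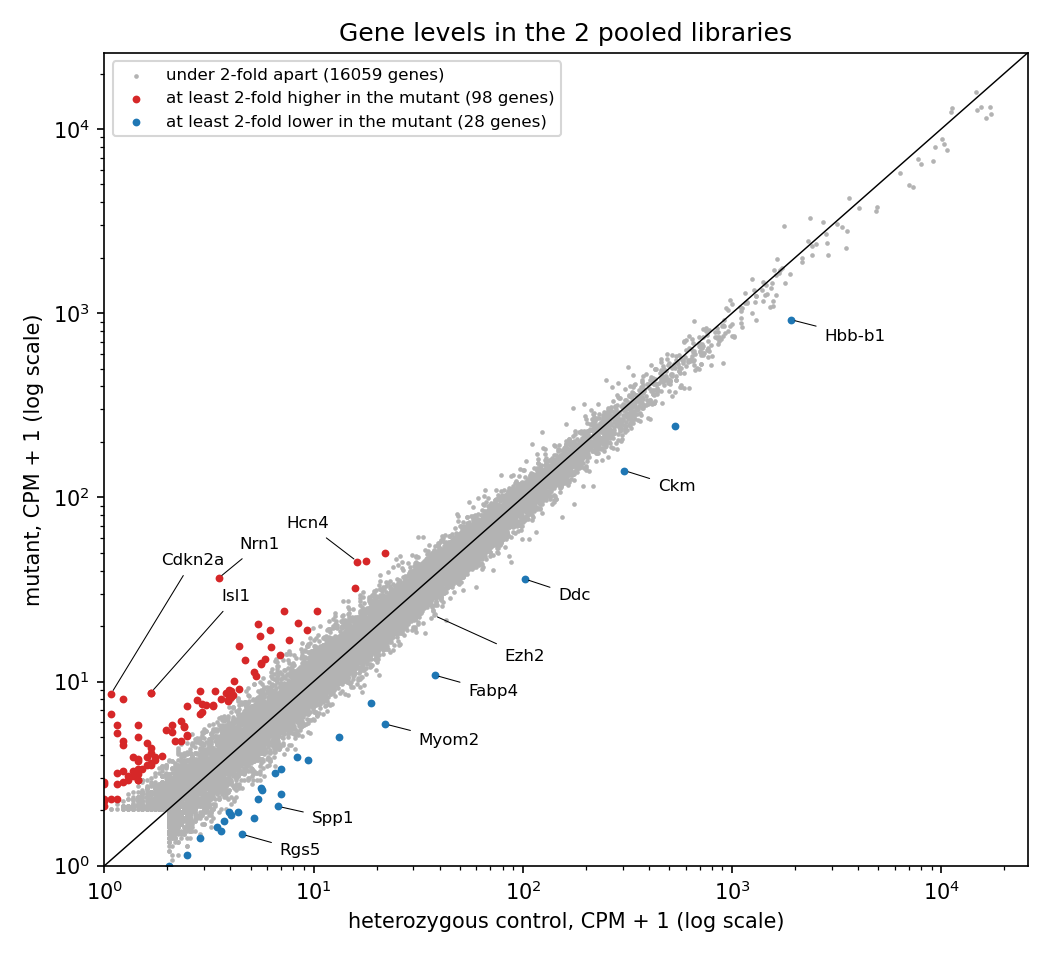
Levels of the 16185 tested genes in the heterozygous control (horizontal) and the mutant (vertical), as CPM + 1 on log scales; each point is 1 gene and the line marks equal levels. The 98 genes at least 2-fold higher in the mutant lie mostly at low heterozygote levels, with a median of 1.33 CPM.

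Developmental transcription factors listed beforehand as non-cardiac made up part of this group, although 1 of those listed, Tbx1, is also on the list of cardiac progenitor genes. Of 80 such genes listed, 12 reached 1 CPM; their median log2 ratio was 0.97, at percentile 100, and 6 were at least 2-fold higher and 0 lower. A gene can reach this floor through its mutant level alone, and such a gene can be counted as higher but not as lower. Otx2, Otx1 (0.22 CPM in the heterozygote), Pax6 (0.44 CPM), Dlx5 and Alx1 did so, while Msx2 had 1.77 CPM there. Of the listed genes, 30 had no read in either library. Over all 79 genes in the table the median was 0.06 at percentile 100; among the 12 it was 0.30 with a pseudocount of 5 CPM and 1.76 with counts under 3 set to 3 and no pseudocount. Otx2, a regulator of head and forebrain development, had 82 reads against 1 (ratio 76.2, 13.3 to 3046), and its relative Otx1 55 against 3 (ratio 17.0, 5.53 to 85.1). The eye regulator Pax6 was 10.8-fold higher (4.74 to 30.5) and the homeobox gene Msx2 3.91-fold (2.49 to 6.38). The remaining pair, named because the count is small, were Dlx5, 7.81-fold higher (3.09 to 25.3), and Alx1, with 19 reads against 0. Alx1 was 5.88-fold higher against a floor of 3 counts. Phox2a and Nkx6-2 of the same list, singled out after their values were seen, had ratios of 1.09 (0.701 to 1.71) and 0.941 (0.785 to 1.13). Hox genes stayed near the floor: 2 of 39 reached 1 CPM, with a median of 0.48 at percentile 89.8, while the median of all 39 was 0.08 at percentile 100, and 16 had no read in either library, which allows up to 3 counts in each. Hoxb3 had 35 reads against 12 and Hoxb2 15 against 12, and 0 were 2-fold apart on the scale used for counting.

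Progenitor and pacemaker genes were higher as groups. All 12 tested genes of cardiac progenitors and the second heart field had log2 ratios above 0, with a median of 0.45 at percentile 99.99 (0.24 over all 18 listed), and 3 were at least 2-fold higher. Isl1, a LIM-homeobox gene of the second heart field, had 112 reads against 9 (11.6-fold, 5.88 to 25.9), and Fgf10, a growth factor of the same field, was 3.04-fold higher (1.94 to 4.91). A second model inside Isl1, named isl1-beta in the table, counts some of the same reads (51 against 3). For Osr1 the symbol covers 2 loci: the odd-skipped related gene on chromosome 12 had 55 reads against 12 (4.26-fold, 2.25 to 8.74), while an unrelated locus on chromosome 9 had 483 against 441. The list median and count above use their sum; with the loci apart the median was 0.58, and the chromosome 12 locus, at a log2 ratio of 1.34, was at least 2-fold higher too. Pacemaker and conduction genes had a median of 0.46, at percentile 100, with 15 of 20 above 0, 5 at least 2-fold higher and 0 at least 2-fold lower. Their median was 0.27 after removal of the GC trend and 0.32 with no filter on low values. Beside Isl1 these were the pacemaker channel gene Hcn4, at 638 against 205 reads (2.89-fold, 2.47 to 3.40), Tbx3 (2.67-fold, 2.12 to 3.38), Tbx2 (2.73-fold, 1.85 to 4.14) and, named because the count is small, Shox2 (2.84-fold, 1.64 to 5.14). Cyclin-dependent kinase inhibitors had a median of 0.35 at percentile 99.8, where Cdkn2a and its neighbour Cdkn2b (26 reads against 2, ratio 12.1, 3.02 to 105) were the 2 of 7 that were 2-fold higher. Members of these lists, Isl1, Pax6, Cdkn2a, Cdkn2b and Hcn4 among them, were known from the published study of this mouse, so these counts are not independent evidence of direction.

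**Figure D2:**
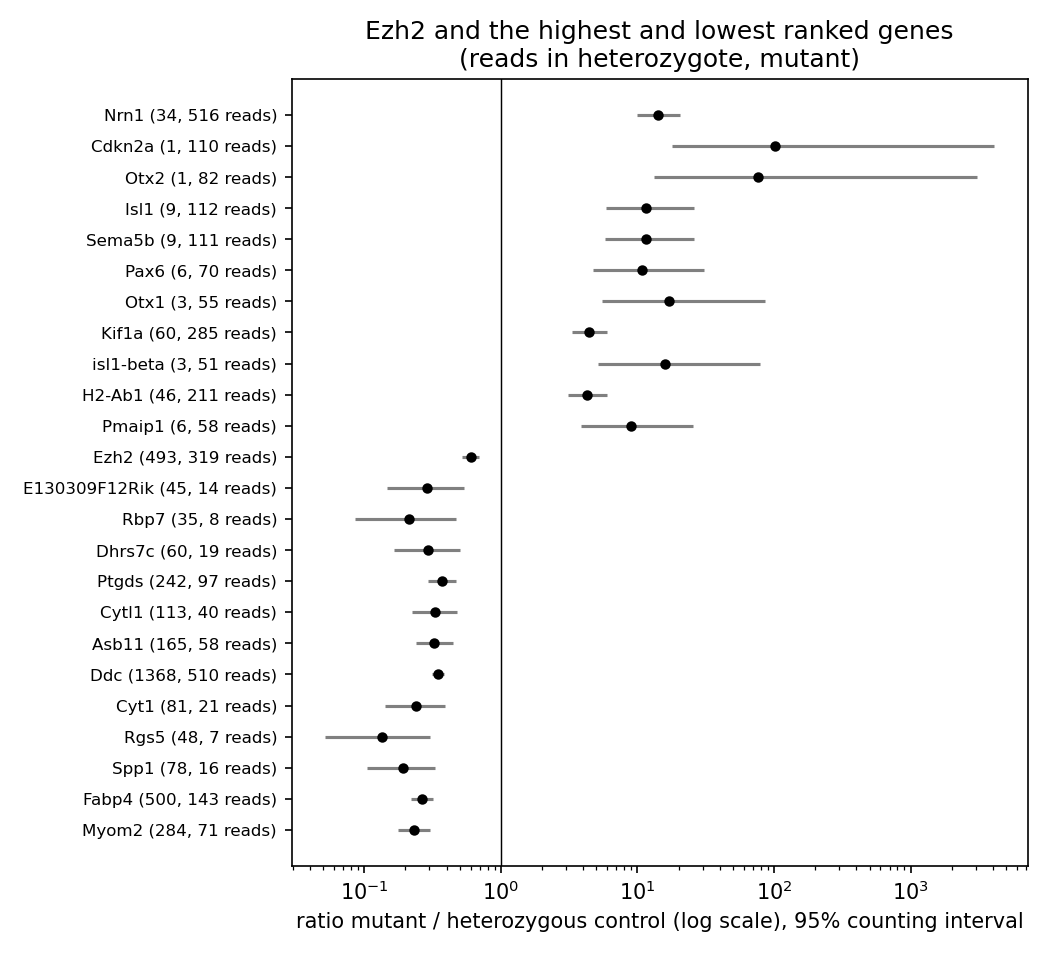
Ratio of scaled reads, mutant over heterozygous control, on a log scale, for the highest ranked genes reported here, Ezh2 and the 12 lowest ranked genes; points are ratios from 1 library per genotype and bars are 95% counting intervals. Read numbers stand beside each name, and all intervals lie on 1 side of a ratio of 1, with Ezh2 at 0.601.

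Genes lower in the mutant were fewer and included muscle, vascular and secreted proteins. Myom2, which encodes an M-band protein of the sarcomere, was 4.30-fold lower (3.31 to 5.67; 71 reads against 284). The fatty acid binding protein gene Fabp4 was 3.76-fold lower (3.12 to 4.56), the secreted phosphoprotein gene Spp1 5.25-fold (3.04 to 9.63) and Rgs5, a pericyte marker, 7.38-fold (3.32 to 19.3). Ddc, the gene of aromatic amino acid decarboxylase, belonged to the same group with 510 reads against 1368 (2.89-fold lower, 2.61 to 3.20). Ratios of heterozygote to mutant were 3.06 (2.26 to 4.204) for Asb11, 2.69 (2.11 to 3.43) for Ptgds, 3.40 (2.0 to 6.03) for Dhrs7c, 4.71 (2.15 to 11.7) for Rbp7 and 3.46 (1.86 to 6.82) for E130309F12Rik. Cytl1 was 3.04-fold lower (2.10 to 4.48), and the Cyt1 model inside it (4.15-fold lower) shares its reads.

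Contractile and calcium handling genes of the ventricle went both ways. Ventricular sarcomere genes had a median of -0.08 at percentile 54.0 and calcium handling genes -0.07 at percentile 43.8, with 9 of 22 and 5 of 14 above 0 and 0 members of either at least 2-fold apart. Under total-count scaling both medians were above 0, at 0.01 and 0.02. That scaling shifts log2 ratios by 0.09, which is wider than the counting intervals of Myl2, Tnnt2 and Atp2a2. Myl2, the ventricular light chain, had a ratio of 0.858 (0.852 to 0.863), and Myh7 1.15 (1.14 to 1.16). Atp2a2, the calcium pump of the sarcoplasmic reticulum, had 1.10 (1.07 to 1.12) and Slc8a1, the sodium-calcium exchanger, 0.814 (0.799 to 0.829). Removal of the GC trend took the log2 ratio of Myl2 from -0.22 to -0.04 and that of Myh7 from 0.20 to 0.006. Those of Atp2a2 (0.14 to 0.12) and Slc8a1 (-0.30 to -0.25) changed less. Members farther from 1, singled out after their values were seen, were Myh6 at 1.40 (1.38 to 1.42) and Myoz2 at 0.591 (0.556 to 0.629) among sarcomere genes, and Pln at 0.591 (0.574 to 0.608), Trdn at 0.644 (0.613 to 0.677) and Casq2 at 0.667 (0.621 to 0.716) among calcium handling genes. Cardiomyocyte transcription factors had a median of 0.13 at percentile 99.7, with 14 of 18 above 0 and Tbx20 at 1.20 (1.15 to 1.26) but Hopx at 0.821 (0.783 to 0.861). Skeletal muscle and stress-associated sarcomere genes had 0.19 at percentile 99.7, yet the only 2-fold member, muscle creatine kinase (Ckm), was 2.20-fold lower (2.08 to 2.32). Once the trend with GC content was removed, these last 2 lists had medians of 0.05 and 0.09, at percentiles 96.8 and 94.98. The log2 ratio of Hopx then went from -0.28 to -0.08 and that of Tbx20 from 0.26 to 0.31. With no filter on low values the skeletal muscle list had 0.09 at percentile 96.4. Compact myocardium genes had a median of 0.21 at percentile 99.6, with Ccnd2 at 1.18 (1.15 to 1.21) but Tnnt2 at 0.908 (0.8995 to 0.917). Trabecular genes had 0.04 at percentile 86.4 (-0.04 after removal of the GC trend) and atrial genes 0.09 at percentile 92.1 (-0.03 with a floor of 5 CPM, and percentile 97.95 after removal of the GC trend). Nppa, on both lists, had a ratio of 0.920 (0.909 to 0.931), the trabecular gene Cited1 1.18 (1.14 to 1.22) and the atrial light chain Myl7 1.67 (1.64 to 1.70).

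Genes of S phase and mitosis had a median of -0.14 at percentile 0.39, with 27 of 36 below 0, and of -0.05 under total-count scaling and -0.09 after removal of the GC trend. The DNA topoisomerase gene Top2a had a ratio of 0.858 (0.827 to 0.890) and Mki67 0.988 (0.946 to 1.03), the latter with a log2 ratio above 0 under total-count scaling. G1 cyclins and growth genes had 0.09 at percentile 96.4, and -0.01 after removal of the GC trend. BMP and TGF-beta pathway genes had a median of 0.16 at percentile 99.6, with Bmp7 at 1.27 (1.17 to 1.37), the receptor gene Bmpr1a at 0.892 (0.828 to 0.962) and Bmp10, a trabecular growth factor known from the published study, at 0.869 (0.800 to 0.944). Notch and Wnt pathway genes had 0.21 at percentile 99.8 (94.2 after removal of the GC trend), and the 2 members at least 2-fold higher both belong to the Wnt pathway: the nuclear effector Lef1 (3.40-fold, 2.18 to 5.46) and the secreted modulator Sfrp2 (2.74-fold, 2.08 to 3.63). p53 target and apoptosis genes had a median of 0.14 at percentile 98.3, with Pmaip1 as the 1 member at least 2-fold apart. Imprinted genes had 0.09 at percentile 99.4, where Igf2 had a ratio of 1.11 (1.11 to 1.12) and H19 1.08 (1.07 to 1.08). Removal of the GC trend took the log2 ratio of Igf2 from 0.15 to -0.008 and that of H19 from 0.10 to 0.03. Immediate early and heat shock genes, which respond to tissue handling, had 0.12 at percentile 93.2, with Jun at 1.22 (1.13 to 1.31) but Ctgf at 0.649 (0.591 to 0.712). The BMP and TGF-beta list was at percentile 95.6 with no filter on low values, the p53 list at 94.7 with a floor of 5 CPM, and the imprinted list inside the central 95% of random lists that were not matched on expression.

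**Figure D3:**
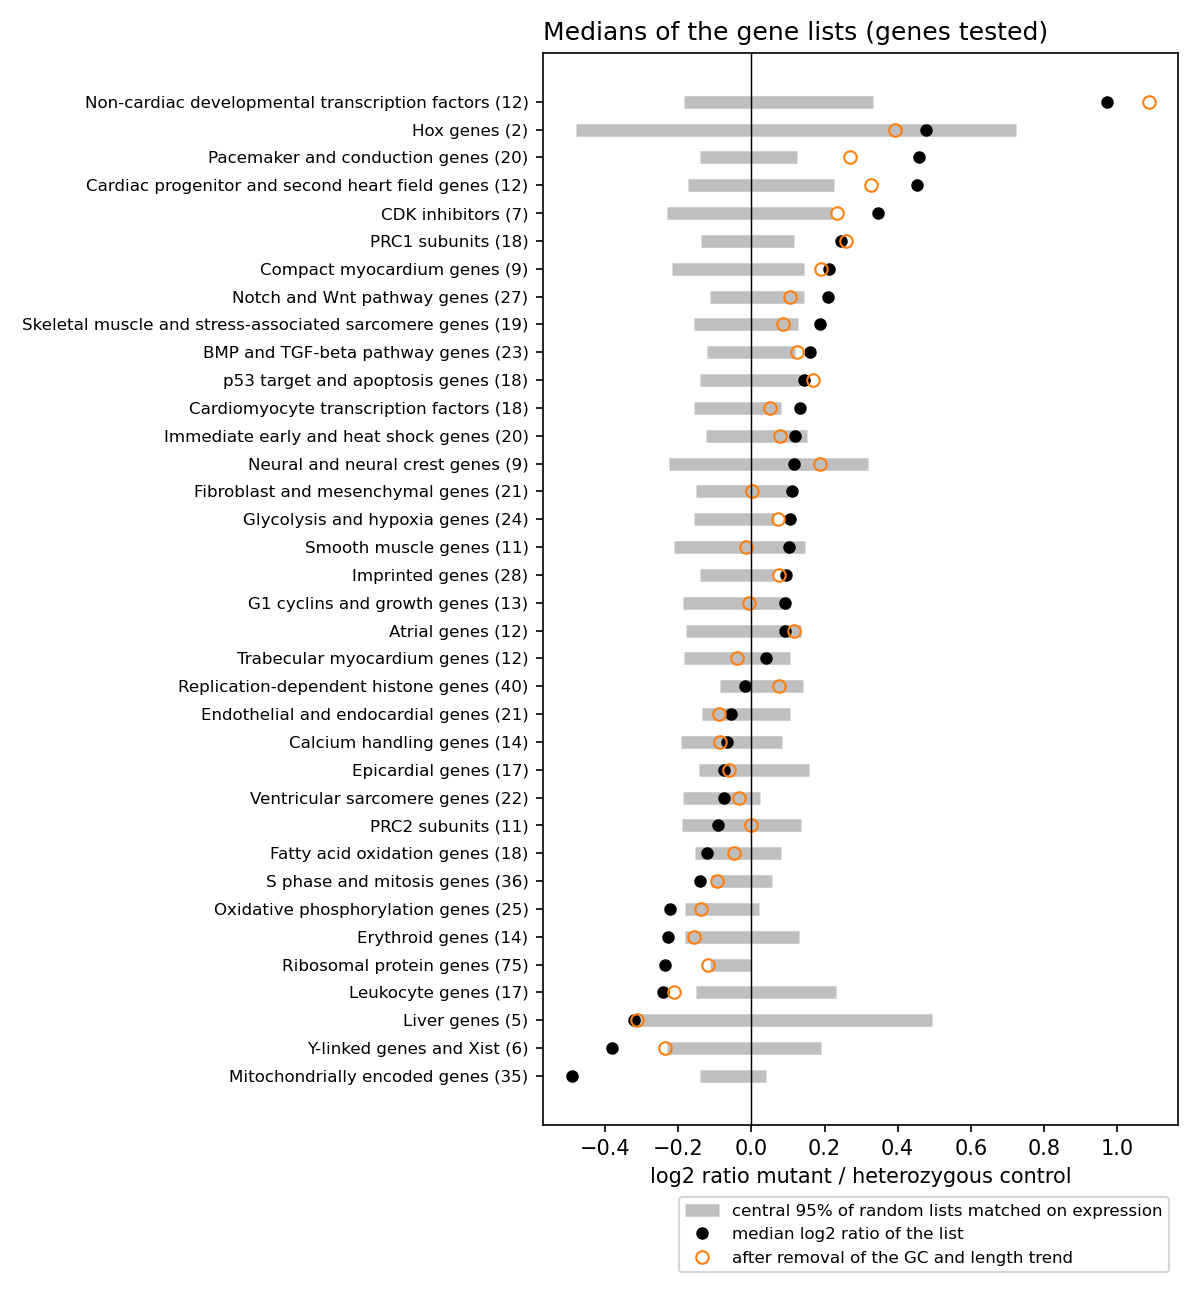
Median log2 ratio, mutant over heterozygous control, of each of the 36 gene lists (black), with the number of genes tested in brackets; grey bars are the central 95% of medians of 10000 random lists matched on expression, and open circles are medians after removal of the GC and length trend, left out for the mitochondrially encoded genes because 13 of 35 have a GC value. Non-cardiac developmental transcription factors are farthest above 0, at 0.97, and mitochondrially encoded genes farthest below, at -0.49.

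Mitochondrially encoded, oxidative phosphorylation and ribosomal protein genes were lower as groups. Mitochondrially encoded genes had a median of -0.49 at percentile 0, with 35 of 35 below 0. This value was not kept after removal of the GC trend in the 13 members with a GC value, whose median was then 0.09 at percentile 99.6; mt-Co1 went from -0.39 to -0.10 and mt-Co2 from -0.52 to -0.08. With under 80% of the list covered that check is void, and the dependence of this list on GC content is not settled. Mitochondrially encoded genes took 12.9% of reads (Wilson 95% interval 12.91 to 12.95) in the heterozygote and 10.7% (10.64 to 10.68) in the mutant. Nuclear genes of oxidative phosphorylation had a median of -0.22 at percentile 0.32, with 20 of 25 below 0. Atp5a1 had a ratio of 0.890 (0.873 to 0.907) and Atp5b 1.02 (1.0001 to 1.04), and Cox5a, singled out after its value was seen, was 1.46-fold higher (1.41 to 1.52). Ribosomal protein genes had -0.24 at percentile 0, with 74 of 75 below 0, Rpl8 at 0.929 (0.906 to 0.952) and Rpl41 at 0.753 (0.734 to 0.772). Under total-count scaling the oxidative phosphorylation and ribosomal protein medians were -0.13 and -0.15, and after removal of the GC trend -0.14 and -0.12. Fatty acid oxidation genes had -0.12 at percentile 8.30 (-0.05 at percentile 29.9 after removal of the GC trend), with Hadha at 0.849 (0.818 to 0.882) and Fabp3 at 0.807 (0.775 to 0.839), and glycolysis and hypoxia genes 0.10 at percentile 99.7 (96.3 without matching on expression), with Aldoa at 1.05 (1.03 to 1.07) and Pkm at 0.987 (0.965 to 1.01). Replication-dependent histone genes had -0.02 at percentile 22.9, a median that was above 0 under median-centred, upper-quartile and total-count scaling, and at 0.08 and percentile 85.5 after removal of the GC trend. Hist1h2ao had a ratio of 1.08 (1.05 to 1.10) and Hist1h2ag 0.982 (0.914 to 1.05). Across 10759 genes, which are not independent replicates, the log2 ratio followed the GC content of the transcript with a Spearman rho of 0.44, and with its length of 0.15. The median log2 ratio went from -0.18 in the tenth of genes lowest in GC to 0.17 in the highest.

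**Figure D4:**
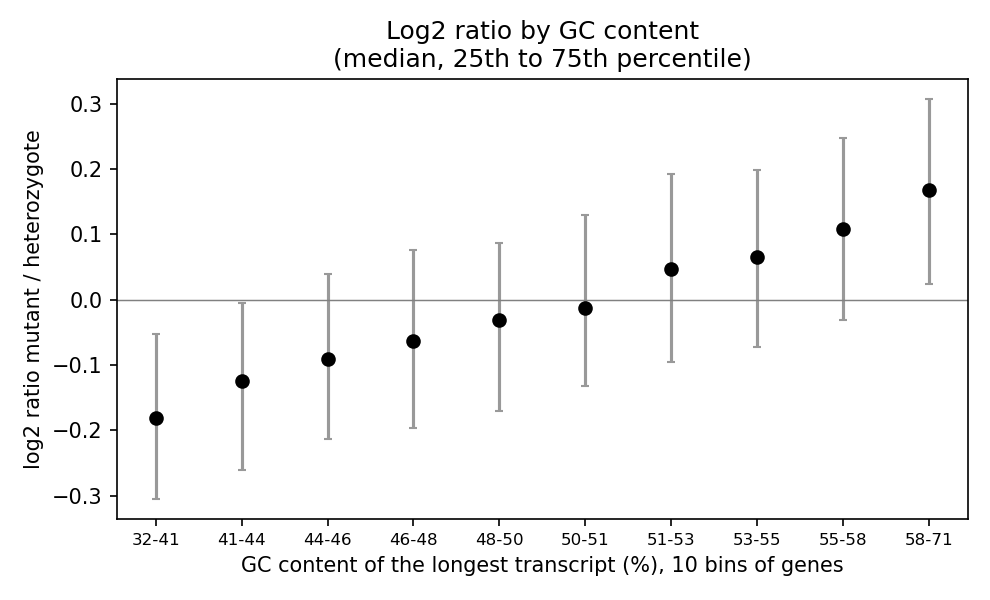
Log2 ratio, mutant over heterozygous control, in 10 bins of genes ordered by the GC content of the longest transcript; points are medians over about 1076 genes each and bars reach from the 25th to the 75th percentile. The medians go up from -0.18 to 0.17.

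Markers of other cell types in the tissue were compared in the same way. Leukocyte genes had a median of -0.24 at percentile 0.12 (-0.16 under total-count scaling). S100a9, a neutrophil gene, had 0 reads against 14, which is 5.02-fold lower against a floor of 3 counts. Its counting interval for heterozygote over mutant starts at 3.57. Erythroid genes had -0.23 at percentile 0.50, with -0.15 under total-count scaling and -0.11 at percentile 5.6 with no filter on low values; the adult globin Hbb-b1 was 2.08-fold lower (2.03 to 2.12), and globins took 1.31% (1.30 to 1.31) of reads in the heterozygote and 0.939% (0.934 to 0.944) in the mutant. Hbb-b1 has near-identical copies, and how the counting split their reads is not given in the sources used here. Endothelial and endocardial genes had -0.06 at percentile 26.0 (-0.09 at 4.57 after removal of the GC trend), with Cdh5 at 0.929 (0.885 to 0.976) and Npr3 at 0.966 (0.910 to 1.03), and epicardial genes -0.07 at percentile 14.5, with Tbx18 at 1.22 (1.09 to 1.37) but Upk3b at 0.934 (0.848 to 1.03); both medians and Npr3 were above 0 on the log2 scale under total-count scaling. Smooth muscle genes had 0.10 at percentile 92.4 (-0.01 after removal of the GC trend), with Rgs5 the 1 member at least 2-fold apart. Fibroblast and mesenchymal genes, with Fn1 at 1.12 (1.10 to 1.14) but Vcan at 0.861 (0.834 to 0.888), had 0.11 at percentile 98.3 and 0.00 at percentile 69.1 after removal of the GC trend, and were at percentile 95.1 without matching on expression. Neural and neural crest genes had 0.12 at percentile 72.5 (0.19 at 89.2 after removal of the GC trend), where Nefm, a neurofilament gene, was the 1 of 9 at least 2-fold higher (3.82-fold, 2.26 to 6.80). Liver genes, with 5 tested, had -0.32 at percentile 2.54, with Apoc1 at 1.14 (0.714 to 1.82) and Trf at 0.802 (0.644 to 0.998). After removal of the GC trend the liver list had -0.31 at percentile 2.02, so whether it lies outside the central 95% depends on the setting.

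The sex composition of the pools differed. Xist, the noncoding RNA of the inactive X chromosome, was 1.73-fold higher in the mutant (1.65 to 1.80; 6267 reads against 3375), and the overlapping antisense Tsix 1.71-fold, where reads cannot be assigned without strand. The Y-linked genes had mutant-to-heterozygote ratios of 0.578 (0.458 to 0.729) for Uty, 0.678 (0.593 to 0.774) for Ddx3y, 0.720 (0.620 to 0.834) for Eif2s3y and 0.797 (0.656 to 0.967) for Kdm5d. The list of Y-linked genes and Xist had a median of -0.38 at percentile 0.05 (-0.24 after removal of the GC trend). Of its 6 tested members Xist and Tsix were above 0 and the 4 Y-linked genes below. The median therefore reflects the make-up of the list and does not measure sex composition. Of 549 tested genes on the X chromosome 0 were at least 2-fold higher and 1 lower (Asb11), and on the Y chromosome 0 were at least 2-fold apart.

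The authors' deposited table gives a p-value for each gene model from the reads of these 2 libraries, so it compares the libraries and not the genotypes. Of 16280 gene models with a deposited CPM of at least 1 in a library, 2990 had a p-value under 0.001 in the authors' deposited table. Among these the authors' deposited table lists 200 with a ratio of heterozygote to mutant of 0.5 or less and 38 with a ratio of 2 or more. For Ezh2 the authors' deposited table gives a ratio of 1.57 with a p-value of 2.87e-10.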

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

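The removal of the GC and length trend, the limit to symbols, to 1 model per overlapping group and to counting intervals, the floor of 3 counts, the separation of Osr1 loci and the leaving out of mitochondrial, globin and sex-chromosome genes were chosen after seeing the data. Depth limits the counts, since 45 of the 98 higher genes had under 1 CPM in the heterozygote, and a larger pseudocount shrinks ratios of such genes by construction.

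The numbers of genes higher and lower were 98 and 28 as reported, 312 and 143 with a pseudocount of 0.1, 165 and 62 with 0.5 and 14 and 6 with 5. They were 50 and 14 with a floor of 5 CPM, 559 and 305 at 1.5-fold and 18 and 4 at 3-fold, each by construction. Under the other scalings there were 98 to 111 higher and 23 to 28 lower genes, and higher genes made up 77.95% to 82.8% of those counted, against 77.8% as reported. With the GC and length trend removed, 66 symbols were higher and 20 lower, and 62 of 81 and 17 of 20 were shared with the uncorrected sets. One model per overlapping group left 87 and 25, and without mitochondrial, globin and sex-chromosome genes there were 98 and 26.

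The Ezh2 log2 ratio ranged from -0.73 with a pseudocount of 0.1 to -0.58 with the trend removed. Of 36 lists, 21 lay outside the central 95% of random lists and 18 to 22 did so under every alternative. Under each of the other scalings 21 of 21 kept their side relative to random lists. Total-count scaling shifts log2 ratios by 0.09, and 35 of the 85 named genes other than Ezh2 moved beyond their counting interval under it. With the trend removed 16 of 20 lists kept their side, and the exceptions were the cardiomyocyte factor, fibroblast, Notch and Wnt, and skeletal muscle lists. With no filter on low values, and over all members, 18 of 21 did, without the BMP and TGF-beta, erythroid and skeletal muscle lists. Against random lists not matched on expression 18 of 21 did, without the fibroblast, glycolysis and imprinted lists. With a floor of 5 CPM 20 of 21 did, without the p53 list, and with a pseudocount of 5 20 of 21, without the skeletal muscle list. The causes were not tested. With counts under 3 set to 3 and no pseudocount 21 of 21 kept their side. Of the 12 highest and 12 lowest genes, 8 and 6 stayed with a pseudocount of 0.1, and 12 and 11 with total-count scaling.

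The single-sample tables held the same values and gave no separate result, and an alternative on deposited intervals was not run because the tables used here list none. No paired analysis was possible because each genotype has 1 library.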

Other observations

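The tests on the genes 2-fold higher, on sex composition, on neural tissue and on the globins were chosen only after the results were seen, as were the genes singled out in the next paragraph; the tests on the GC trend and on neighbouring genes were fixed before their results.

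Several genes are given as single values and were not tested as groups. Gpihbp1, which anchors lipoprotein lipase on capillaries, had 34 reads against 81 (ratio 0.390, 0.253 to 0.589). Cav1, the main protein of caveolae, had 637 against 1170 (ratio 0.506, 0.459 to 0.558), and the fatty acid transporter Cd36 a ratio of 0.695 (0.632 to 0.765). Pecam1, present on endothelium in general, had 0.872 (0.808 to 0.941). Within the MHC region, H2-Ab1 (4.26-fold) and the class I gene H2-K1 (1.95-fold, 1.61 to 2.38) were higher, while H2-D1 had a ratio of 1.10 (0.902 to 1.34), H2-Eb1 1.39 (0.710 to 2.81) and the class II chaperone Cd74 1.22 (0.606 to 2.5); how reads were split among related MHC genes, or with the IAP model that overlaps H2-Ab1 and H2-Eb1, is not given in the sources used here. Tcf7, a relative of the Wnt effector Lef1, was 2.41-fold higher (1.67 to 3.53).

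Higher genes outnumbered lower ones, 98 to 28, and developmental regulators with few reads in the heterozygote, such as Otx2 (1 read) and Pax6 (6 reads), were among them. After removal of the GC and length trend 62 of 81 higher genes stayed 2-fold higher. Medians along GC content spanned only -0.18 to 0.17, so genes well past a log2 ratio of 1 could hardly drop out. The count adds little to the small size of the trend, which argues against it as the whole cause. Sex composition is argued against because Xist, made in female cells only, differed by 1.73-fold (1.65 to 1.80), less than any of the 98 higher genes. For the regulators, neural tissue was not settled. Of 18 listed neural genes 0 gained as many CPM as Otx2 (5.56 CPM), and the largest gain was 3.75 CPM, for Nefm. That bar was the gain of 1 regulator chosen after the results, and Nefm gained more than Otx1 (0.222 to 3.78 CPM). The median gain of the 18 was 0.13 CPM. Among them Stmn2 went from 1.40 to 1.10 CPM and Gap43 from 57.4 to 59.0 CPM. Tubb3 went from 0.665 to 1.03 CPM and Elavl3 from 1.11 to 1.92 CPM. Outside that list, Nrn1 went from 2.51 CPM in the heterozygote to 35.4 CPM in the mutant. Kif1a went from 4.44 to 19.6 CPM and Sema5b from 0.665 to 7.62 CPM, each a larger gain than that of Otx2. The Ezh2 genotype may be the cause and was not tested, for lack of replicates. Tissue of other kinds, neural or not, and differences between litters stay open.

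The log2 ratio followed GC content across genes, with a rho of 0.44. A trend carried by strongly raised GC-rich genes alone is argued against. Among 3360 genes with at least 50 CPM and a log2 ratio within 0.5 of 0, rho was 0.47. A small rise of many GC-rich genes would stay inside that limit and was not tested. A GC bias between the libraries is a candidate explanation: within the ribosomal protein genes rho was 0.30 (bootstrap interval 0.09 to 0.49, 75 genes). The ribosomal protein median was still at -0.12 and percentile 0 after the trend was removed, so the trend leaves part of that difference open.

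Adult globins were lower by more than embryonic ones, with log2 ratios of -1.05 for Hbb-b1 and -0.61 for Hba-a2 against -0.48 for Hbb-y, -0.22 for Hbb-bh1 and -0.02 for Hba-x. Less blood in the mutant pool would lower all by 1 factor, which the difference of means of -0.59 argues against as the whole cause. The GC and length trend is argued against for the alpha globins, since Hba-a2 minus Hba-x was -0.58 before its removal and -0.54 after. Younger embryos in the mutant pool could not be told apart from the genotype: Tnni3, which replaces Tnni1 as the heart matures, had a log2 ratio that differed from that of Tnni1 by -0.12, and the labels give 1 age for both pools. Reads shared between globin copies and an effect of the genotype stay open.

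For a hypothesis that higher genes lie in shared domains, the number of neighbouring pairs was not above the central 95% of random sets. It was at the upper edge of that range, and with so few pairs the comparison cannot exclude such domains. Of the 84 higher symbols, 3 pairs without overlap lay within 100 kb of each other (Cdkn2a with Cdkn2b, Pcsk4 with Reep6, Lmtk3 with Grin2d), against a median of 1 pair and a central 95% of 0 to 3 in 10000 random sets matched on expression.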
